A study of Homo sapiens with 17 samples.

How the data were processed

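RNA sequencing and RNA polymerase II (Pol II) ChIP-seq were analysed from HEK293 Flp-In T-REx cells, a human embryonic kidney line that takes up an inducible transgene at a single site. Per the labels' protocols, doxycycline at 100 ng per ml induced a short hairpin against the endogenous DIS3 together with an exogenous DIS3 that was wild type (WT), mutated in the PIN endonuclease domain (D146N), mutated in the RNB exonuclease domain (D487N) or mutated in both (double mutant). The labels' protocols describe total RNA extracted with TRI reagent, treated with Turbo DNase, depleted of ribosomal RNA with Ribo-Zero, mixed with ERCC spike-ins and made into TruSeq libraries. Chromatin was cut with micrococcal nuclease and precipitated with the Pol II antibody 8WG16, per the labels' protocols, and a mock precipitation accompanied each genotype. RNA was measured in triplicate in the 4 genotypes, WT and the double mutant were also sequenced deeper, and Pol II and mock ChIP-seq covered WT and the double mutant with 3 libraries each. The PAR-CLIP libraries of the RNB mutant were not analysed here.

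The deposited RNA and ChIP tables hold raw read counts per annotated transcript or region, as tested on the whole numbers in the files and as the submitters' processing notes describe them. The submitters' processing notes name CASAVA 1.8.2, cutadapt 1.2.1 and Cufflinks 2.1.1 for RNA, and Bowtie2, SAMtools 0.1.19 and bedtools 2.23.0 for ChIP, without giving the role of each. They give hg19 as the genome build, and the ChIP notes also name GRCh37. The counting tool is not stated. There were 199309 entries per RNA library and 200078 entries for ChIP, and a read was counted for every isoform it overlapped, as checked on the file totals. In the mock libraries counts followed the span of a transcript (Spearman's rho 0.971 over 110833 transcripts) more closely than its exonic length (0.359). RNA counts separated the strands: over 34 nested opposite-strand pairs the median ratio was 0.0123, and 2 pairs reached 0.5. The merged transcript assembly of 937538 transcripts carried no counts and was not used for them. No ERCC entry was found in the tables, so scaling by spike-ins was not run.

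Isoforms were collapsed to the isoform with the most standard-depth counts, which left 61883 features. These were 57388 genes, 2471 regions of 3000 nt that the authors' tables list upstream of genes, 1399 regions downstream of small nucleolar RNAs (snoRNAs) and 625 tRNA genes. The regions downstream of snoRNAs had a median length of 12112 nt (17 to 1579068 nt). Of these regions 864 ended within 10 nt of an annotated transcript start on the same strand. Their counts therefore need not come from extended snoRNAs. The upstream regions are called PROMPT regions here, for promoter upstream transcripts, because 2441 of them began within 500 nt of a transcript start on the opposite strand. Genes were classed from their symbols as protein-coding (19102), clone-named (22357, mostly unnamed noncoding transcripts), snoRNA or scaRNA (1467) and other (14462). Of 55387 symbols, 32535 matched a reference table of names. Clone-named genes were split into those starting within 3 kb upstream of a protein-coding gene on the opposite strand, those within 5 kb downstream, those overlapping another gene and those elsewhere.

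Counts were tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood test (edgeR QL below), with TMM normalisation, the filterByExpr filter and Benjamini-Hochberg adjustment (BH) at 0.05. The 4 genotypes at standard depth shared 1 fit, and deep RNA, Pol II and Pol II with mock had their own. The RNA contrasts were double mutant, PIN and RNB against WT, RNB against PIN, double mutant against RNB, and the PIN by RNB interaction (double mutant minus RNB minus PIN plus WT). The ChIP contrasts were double mutant against WT in the Pol II precipitation (IP), IP against mock in each genotype, and the difference of IP over mock between genotypes. CPM values used library sizes scaled by the TMM factors of the fit, and shares of a library in percent were not scaled. Errors of log2 fold changes are approximate, and too small at few counts. Deep libraries were resequenced standard libraries and were never pooled with them: chi-square per degree of freedom was 1.10 to 1.25 between standard and deep libraries of the same number, and 2.715 to 13.16 between other numbers.

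Gene sets were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry as alternatives. Each list is reported by its median log2 fold change, the numbers called over all features, and the numbers adjusted over the list alone. The 25 lists were exosome subunits and cofactors, snoRNA host genes, snoRNA and scaRNA genes, spliceosomal snRNA genes, short Pol III RNAs, replication-dependent histone genes, nuclear long noncoding RNAs, paraspeckle proteins, p53 target genes, integrated stress and unfolded protein response, heat shock response, interferon-stimulated and RNA-sensing genes, immediate early genes, mitotic genes, DNA replication genes, cytoplasmic ribosomal protein genes, ribosome biogenesis genes, mitochondrially encoded genes, oxidative phosphorylation genes, cholesterol synthesis genes, hypoxia and glycolysis genes, neuronal genes, markers of blood cells, markers of fibroblasts and epithelia, and kidney lineage and HEK293 markers. The lists, the contrasts, the alternatives and the rule for naming genes were set before the data were examined. That rule took DIS3, the 8 largest rises and 8 largest falls among genes with a symbol, a mean CPM of at least 1, an adjusted p under 0.05 and no overlap between groups, up to 4 members of each list with the smallest p, and 4 rises and 2 falls among loci without a symbol. Members of the DUX4L family on chromosome Y were left out, and the NEAT1 isoforms were chosen after their values were seen. Genes that share reads with near-identical copies (snoRNA, snRNA, histone and DUX4L families) have uncertain counts.

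RNA changes were set against Pol II changes by the median Pol II change of RNA-called features, as a percentile among 10000 random lists matched in 20 bins of Pol II signal. Comparisons that share WT libraries were set beside 10 simulations in which the libraries of all groups, WT included, were drawn anew from the WT means. A fold against a group with 0 counts was computed against a floor of 3 counts over the group, which covers counting error only, as PCR reads are not independent molecules.

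The alternatives were RLE size factors, library size only for ChIP, DESeq2 1.42.0 with its Wald test, no filter, a filter of CPM 1 in 3 libraries, fits of the compared groups only, a replicate block, upstream windows of 1 and 5 kb, an absolute log2 fold change of at least 1, and each library left out in turn. TMM factors from protein-coding genes, isoform counts summed per gene, the long NEAT1 isoform without the reads of the short one and, for Pol II set against RNA, the replicate block and the features with the IP above the mock were added after the data were seen. Numbers were taken to pair WT with double mutant at standard depth (0.158 to 0.301), deep (0.376 to 0.593) and in Pol II IPs (0.270 to 0.760). There same-numbered deviations from group means (mean CPM at least 10) correlated above 0.1 for every number. Yet double-mutant IP 2 followed WT IP 3 (0.662) more than WT IP 2 (0.531). The mocks (0.00584 to 0.367) and other pairs of genotypes (-0.22 to 0.130) were not paired.

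The pipeline was tested on simulated data with 200 changed features, up or down at random, and all others unchanged. In the real double mutant 18970 of 24007 features were called at standard depth. The rates below therefore do not carry over to contrasts in which most features changed. At standard depth it recovered 76.0% of 2-fold and 92.9% of 4-fold changes for double mutant against WT (21249 features), 81.1% and 94.9% for PIN against WT (21416) and 51.1% and 87.0% for the interaction (21337). It recovered 91% and 99% at deep coverage (36037), 97% and 100% for Pol II (51547), and 76% and 100% for IP over mock (53457). False calls were 8.89% of the calls for double mutant against WT at standard depth, 7.37% for IP over mock, 6.40% at deep coverage and 5.03% for PIN, above the nominal 5%, and 4.83% for Pol II and 3.03% for the interaction.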

Results

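RNA was measured in 3 libraries of each of 4 DIS3 genotypes (WT, PIN, RNB and double mutant), with 3 deeper runs of the WT and double-mutant libraries. Pol II occupancy was measured in 3 IP and 3 mock libraries of WT and of the double mutant. DIS3 is the processive nuclease of the nuclear exosome, the complex that trims and destroys nuclear RNA from its 3' end. Its RNB domain removes nucleotides 1 at a time and its PIN domain cuts inside the RNA. At standard depth the counts over all features were 7155080, 7074151 and 7932501 in WT, 6875603, 6559622 and 7043512 in PIN, 6227876, 7212976 and 7672619 in RNB, and 3059869, 2378121 and 4007602 in the double mutant. The deep runs held 45187388, 47354397 and 51855786 counts in WT and 18111805, 15240573 and 23732244 in the double mutant. The Pol II IPs held 49484465, 61741760 and 62858113 counts in WT and 48739028, 66211685 and 62853643 in the double mutant. The mocks held 43971002, 49080370 and 52050679 in WT and 31707632, 46472569 and 45043864 in the double mutant. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between libraries, and each genotype was a single cell line, so genotype and line could not be separated.

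DIS3 itself (chromosome 13, 73329540 to 73356071, minus strand, hg19) was read first in each sample, because the endogenous copy was depleted and a transgene expressed. The counts could not separate the endogenous from the exogenous message, so they check only that DIS3 RNA was present. At standard depth DIS3 stood at 828 ± 35 CPM (SD, n = 3) in WT, 725 ± 42 in PIN, 929 ± 15 in RNB and 1170 ± 183 in the double mutant. DIS3 was higher in the double mutant than in WT (log2 fold change 0.50 ± 0.09, edgeR QL, BH-adjusted p = 2.7e-06), and no difference passed the test in PIN (-0.19 ± 0.08, adjusted p = 0.15) or RNB (0.17 ± 0.08, adjusted p = 0.12). In a fit over all transcripts with its own TMM factors the same DIS3 transcript passed it in RNB (0.24 ± 0.07, edgeR QL, BH-adjusted p = 0.006) and in the deep runs (0.57 ± 0.10, adjusted p = 1.9e-05), and of 6 DIS3 transcripts 1 was lower in PIN (ENST00000475871.1, -0.31 ± 0.07, adjusted p = 0.0012). In the deep runs DIS3 stood at 1066 ± 52 CPM in WT and 1060 ± 191 in the double mutant (log2 fold change -0.01 ± 0.13, edgeR QL, BH-adjusted p = 0.96), which was 0.65 above the median protein-coding gene. Without double-mutant replicate 3 the deep DIS3 value was -0.29 (edgeR QL, BH-adjusted p = 0.035), and its direction turned with the scaling (0.64 with TMM factors from protein-coding genes, -0.58 with DESeq2). Pol II on DIS3 went from 47.9 ± 4.7 to 40.1 ± 2.1 CPM (-0.26 ± 0.08, edgeR QL, BH-adjusted p = 0.076, and 0.0091 with the replicate block). Without WT Pol II replicate 1 or 3 that change passed the test (-0.17, adjusted p = 0.015, and -0.32, adjusted p = 0.032, edgeR QL).

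PROMPT RNA took up more of the libraries when the exonuclease domain was mutated, and RNA downstream of snoRNAs did so mainly in the double mutant. PROMPT regions, which give short antisense transcripts upstream of promoters, held 0.216 to 0.239% of counts in WT, 0.240 to 0.268% in PIN, 1.32 to 1.43% in RNB and 3.32 to 3.54% in the double mutant. Regions downstream of snoRNAs held 0.696 to 0.903% in WT, 0.887 to 1.19% in PIN, 1.06 to 1.23% in RNB and 3.56 to 5.99% in the double mutant. MT-RNR2, the large mitochondrial ribosomal RNA, fell from 9.71 to 10.8% of counts in the other genotypes to 2.56 to 4.13% in the double mutant. The 10 most abundant features together held 15.2 to 19.1% of the double-mutant counts and 26.3 to 27.8% elsewhere.

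**Figure D1:**
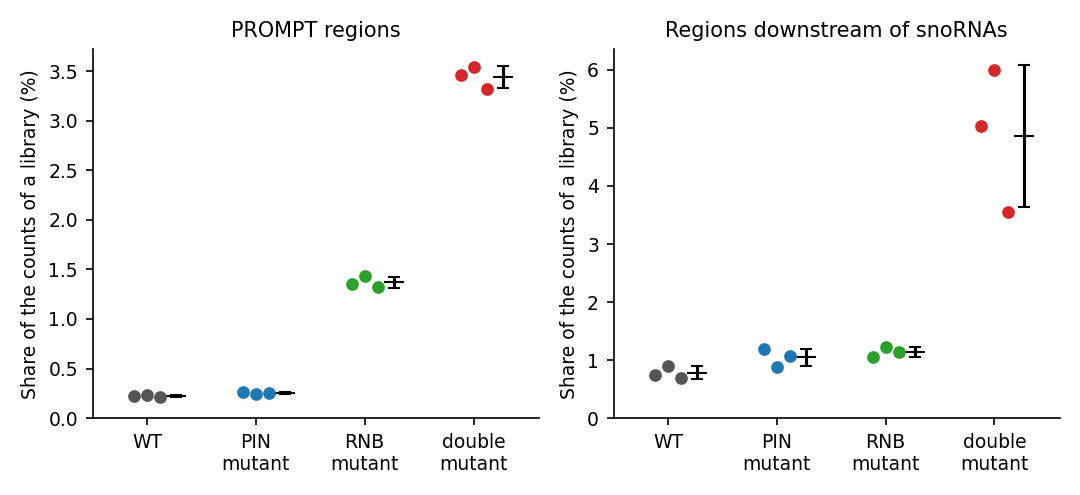
Percent of each standard-depth library's counts (y axis) in PROMPT regions and in regions downstream of snoRNAs, by genotype, with a point for each of 3 libraries and bars for the mean and SD. PROMPT regions held 0.216 to 0.239% in WT and 3.32 to 3.54% in the double mutant.

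To find which RNAs depend on both nuclease activities of DIS3, the double mutant was compared with WT at standard depth. PROMPT RNA accumulated. RNA downstream of snoRNAs rose and most of the listed genes for ribosomal proteins, mitosis, cholesterol synthesis and glycolysis fell, in set calls that did not hold with an estimated inter-gene correlation. Of 24007 features tested, 10120 were higher and 8850 lower (edgeR QL, BH; 10118 and 8858 with the replicate block), and 8307 and 3889 of these by at least 1 log2 unit. Among 15259 protein-coding genes 4104 were higher and 7904 lower, with a median of -0.35. TMM factors taken from protein-coding genes moved all values up by 0.34 and gave 12219 higher and 6282 lower. The groups did not overlap for 19092 features, 79.5% against 10% by chance.

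PROMPT regions were the class that rose most, and 2106 of 2142 were higher and 3 lower (median log2 fold change 3.51; camera adjusted p = 2.5e-46, and 1.2e-05 with an estimated correlation). They were 3.86 above the protein-coding median. Regions downstream of snoRNAs were higher at 871 of 1028 and lower at 35 (median 2.1; camera adjusted p = 5.8e-21, but 0.13 with an estimated correlation). Leaving out those that contain an annotated exon gave 711 higher of 825 (median 2.14). Clone-named genes that start upstream of a protein-coding gene on the opposite strand were higher at 431 and lower at 34 of 541 (median 2.40; camera adjusted p = 5.8e-15, and 5.2e-07 with an estimated correlation). Clone-named genes away from other genes were higher at 567 of 848 (median 1.64; camera adjusted p = 4.2e-07, and 0.035 with an estimated correlation). Genes for snoRNAs and scaRNAs went both ways (91 higher and 49 lower of 208, median 0.47; camera adjusted p = 0.14), as did tRNA genes (9 and 7 of 41, median 0.45; camera adjusted p = 0.75). The directions of these class medians were the same under each scaling.

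**Figure D2:**
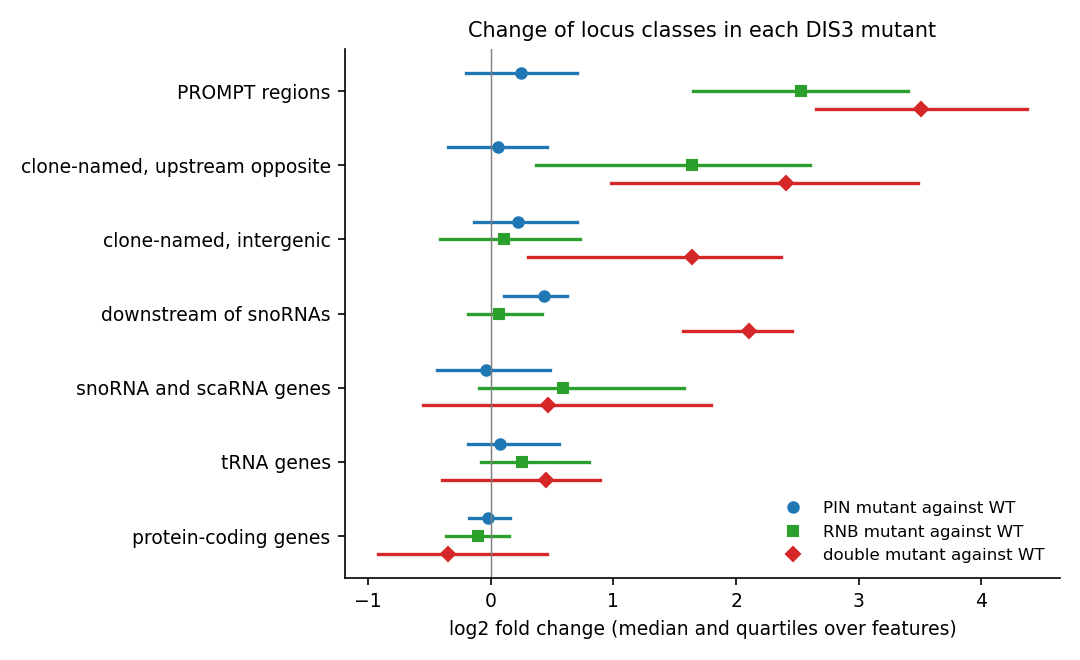
Log2 fold change of classes of features (x axis) in the PIN, RNB and double mutants against WT at standard depth, with points for medians and bars for quartiles over features. PROMPT regions stood at 3.51 in the double mutant, 2.53 in RNB and 0.24 in PIN.

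The PROMPT region beside HSPA5, which encodes the endoplasmic reticulum chaperone BiP, showed the scale of the rise. This region (T3kB_uc004bpn.2, chromosome 9, 128003662 to 128006661, plus strand) went from 0.102 ± 0.088 CPM in WT to 41.1 ± 8.0 in the double mutant (log2 fold change 8.40 ± 0.32, edgeR QL, BH-adjusted p = 1.3e-22), on 2 WT counts. The PROMPT region beside OLA1, an ATPase gene (T3kB_uc002uih.2), had 0 counts in WT and was at least 72.9-fold higher. The one beside the clone-named gene RP4-625H18.2 (T3kB_uc003ncv.1) was at least 38.9-fold higher, and the clone-named gene RP11-505P4.7 at least 45.4-fold higher. Among genes with a symbol, the microRNA genes MIR3191 and MIR4710, the antisense RNA ZFX-AS1, the pseudogene RPS20P35 and DUX4L13, a copy of the DUX4 homeobox repeat, had 0 WT counts and were at least 32.4-fold, 28.6-fold, 28.1-fold, 18.9-fold and 30.8-fold higher. MIR320A (6.94 ± 0.54, edgeR QL, BH-adjusted p = 5.7e-14) and LINC00167 (6.62 ± 0.43, adjusted p = 4e-16) rose from 1 and 2 WT counts. A copy of the U3 snoRNA on chromosome 17 rose by 6.50 ± 0.36 on the log2 scale (edgeR QL, BH-adjusted p = 5.2e-18).

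Genes that fell most included a histone gene, growth-factor and lipid-signalling genes and an antigen-presentation gene. HIST1H3F, a replication-dependent histone H3 gene, fell from 6.69 ± 0.41 to 0.258 ± 0.060 CPM (log2 fold change -4.64 ± 0.47, edgeR QL, BH-adjusted p = 6.5e-11). IGFBP5, which binds insulin-like growth factors, fell from 131 ± 2.4 to 12.9 ± 1.0 CPM (-3.35 ± 0.10, edgeR QL, BH-adjusted p = 1.9e-25). PNCK, a calmodulin-dependent kinase gene (-4.05), ALOX5, which makes leukotrienes (-3.38), ATP6V1B1, a proton-pump subunit (-3.24), CHADL, a cartilage matrix gene (-3.24), and HLA-DPA1 (-3.22) also fell (edgeR QL, BH-adjusted p from 1.6e-13 to 2.6e-06). A Y RNA copy at 11:47748446 (-3.35) and the clone-named AC051649.6 (-3.97) and RP11-380L11.3 (-3.70) fell with no more than 3 counts left in the double mutant.

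Ribosomal protein messages fell as a group. Of 80 genes 73 were lower and 2 higher, also adjusted over the list alone (median -1.46; camera adjusted p = 3.5e-16, but 0.36 with an estimated correlation). RPL31 fell from 574 ± 45 to 94.3 ± 15.0 CPM (-2.59 ± 0.09, edgeR QL, BH-adjusted p = 1e-23), and RPL29 (-2.40), RPL23 (-2.18) and RPL7A (-2.05) followed. Ribosome biogenesis genes were split, 14 higher and 16 lower of 38, also adjusted over the list alone (camera adjusted p = 0.72); their median of 0.03 became -0.01 with DESeq2 and their mean was -0.04. NPM1, the nucleolar chaperone, fell (-1.76) while the processing factors UTP14A (1.64) and RRP12 (0.99) rose (edgeR QL, BH). Mitotic genes were all lower, 28 of 28, also adjusted over the list alone (median -1.11; camera adjusted p = 2.6e-08, but 0.36 with an estimated correlation), including TOP2A, the topoisomerase that unlinks chromosomes (-1.85), and MKI67 (-1.52). Replication-dependent histone genes were lower at 26 and higher at 2 of 42, also adjusted over the list alone (median -0.64; camera adjusted p = 0.0005, but 0.66 with an estimated correlation). DNA replication genes were lower at 15 and higher at 8 of 31, also adjusted over the list alone (median -0.17, which became 0.18 with protein-coding factors; camera adjusted p = 0.18).

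Most listed genes of cholesterol synthesis, glycolysis and oxidative phosphorylation were lower, in set calls that did not hold with an estimated correlation. Cholesterol synthesis genes were lower at 21 and higher at 2 of 24, also adjusted over the list alone (median -1.17; camera adjusted p = 9.6e-06, but 0.073 with an estimated correlation). Among them were IDI1 (-2.51), SQLE (-2.12) and HMGCS1 (-1.74), enzymes of the pathway, and INSIG1, its sterol sensor (135 ± 14 to 26.5 ± 4.0 CPM, -2.34 ± 0.10, edgeR QL, BH-adjusted p = 6e-21). Hypoxia and glycolysis genes were lower at 20 and higher at 2 of 26, also adjusted over the list alone (median -0.69; camera adjusted p = 0.00031, but 0.36 with an estimated correlation), with GAPDH at -1.83 and LDHA at -1.54. Nuclear genes of oxidative phosphorylation were lower at 25 and higher at 1 of 34, also adjusted over the list alone (median -0.68; camera adjusted p = 0.0001, but 0.52 with an estimated correlation). Mitochondrially encoded genes parted, 8 higher and 5 lower of 15, also adjusted over the list alone (median 0.60, mean 0.08, camera direction down, adjusted p = 0.99). MT-RNR2 fell (-2.11 ± 0.15, edgeR QL, BH-adjusted p = 2.3e-15) and so did MT-CO1 (-1.73), whereas MT-ND2 rose (1.52 ± 0.14, adjusted p = 4e-12).

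Lists of stress and signalling genes were read next, and no difference between these lists was tested. Immediate early genes, which respond within minutes to growth factors and stress, were higher at 14 and lower at 4 of 24, also adjusted over the list alone (median 0.72; camera adjusted p = 0.095). The transcription factor gene EGR1 rose from 5.09 ± 0.90 to 122 ± 24 CPM (4.60 ± 0.14, edgeR QL, BH-adjusted p = 3.8e-25), JUNB by 2.06 and ATF3 by 1.81, while MYC fell (-1.13). Integrated stress and unfolded protein response genes were higher at 10 and lower at 15 of 27, also adjusted over the list alone (median -0.47, mean 0.09, camera direction down, adjusted p = 0.61), with PPP1R15A (2.58) and TRIB3 (1.79) higher and the chaperone PDIA4 (-1.51) lower. Heat shock genes were lower at 11 of 15, also adjusted over the list alone (median -0.76; camera adjusted p = 0.0013, but 0.36 with an estimated correlation), with HSPA8 at -2.03. The p53 targets were lower at 16 and higher at 4 of 24, also adjusted over the list alone (median -0.67; camera adjusted p = 0.041, but 0.051 with the replicate block and 0.48 with an estimated correlation), with CCNG1 at -1.83 and SESN2 at 1.16. Interferon-stimulated and RNA-sensing genes were mixed, 6 higher and 7 lower of 23, also adjusted over the list alone (median -0.10, mean 0.14, median 0.24 with protein-coding factors; camera adjusted p = 0.49), with the RNA-sensing kinase gene EIF2AK2 at -1.77.

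RNA-processing lists did not move as groups. Exosome subunits and cofactors were lower at 14 and higher at 7 of 26, also adjusted over the list alone (median -0.29, which became 0.05 with protein-coding factors; camera adjusted p = 0.23), with the Ski complex gene TTC37 at -1.28 and the poly(A) polymerase gene PAPD7 at -1.30. snoRNA host genes were split, 7 higher and 11 lower of 22, also adjusted over the list alone (median -0.17, which became 0.18 with protein-coding factors, mean 0.16; camera adjusted p = 0.81), with SNHG10 at 3.01 and SNHG17 at 1.99. The snoRNA and scaRNA list had 89 higher and 47 lower of 203, and 88 and 47 adjusted over the list alone (median 0.48; camera adjusted p = 0.2). SNORD13, which guides ribosomal RNA acetylation, rose from 3.57 ± 0.36 to 119 ± 21 CPM (5.06 ± 0.16, edgeR QL, BH-adjusted p = 5.7e-25), and the U3 gene SNORD3D rose by 4.35. Spliceosomal snRNA genes were higher at 22 and lower at 11 of 41, also adjusted over the list alone (median 1.11; camera adjusted p = 0.18), with RNU1-1 at 3.73 and RNU2-61P at -1.84. Short Pol III RNAs were higher at 2 and lower at 5 of 9 (median -0.57; camera adjusted p = 0.39), with RMRP at -1.27, nuclear long noncoding RNAs were higher at 9 and lower at 4 of 17 (median 0.61; camera adjusted p = 0.38), with MIAT at 1.81, and paraspeckle protein genes were higher at 3 and lower at 9 of 15 (median -0.22, which became 0.13 with protein-coding factors; camera adjusted p = 0.18), with HNRNPA1 at -1.60, all also adjusted over the list alone.

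Lists of cell identity were tested for signs of other cell types or of a change in the line. Neuronal genes were higher at 11 and lower at 6 of 19 (median 1.23; camera adjusted p = 0.72), with NEFL at -2.35 and CHGA at 3.24. Markers of blood cells were higher at 7 of 10 and lower at none (median 1.23; camera adjusted p = 0.1), with ITGAM at 2.53. Markers of fibroblasts and epithelia were higher at 9 and lower at 7 of 18 (median 0.63; camera adjusted p = 0.99), with VIM at -1.14. Kidney lineage and HEK293 markers were higher at 2 and lower at 7 of 12 (median -0.29, which became 0.05 with protein-coding factors; camera adjusted p = 0.18), with CDH2 at -2.02. The counts of these 4 lists were also those adjusted over the list alone.

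**Figure D3:**
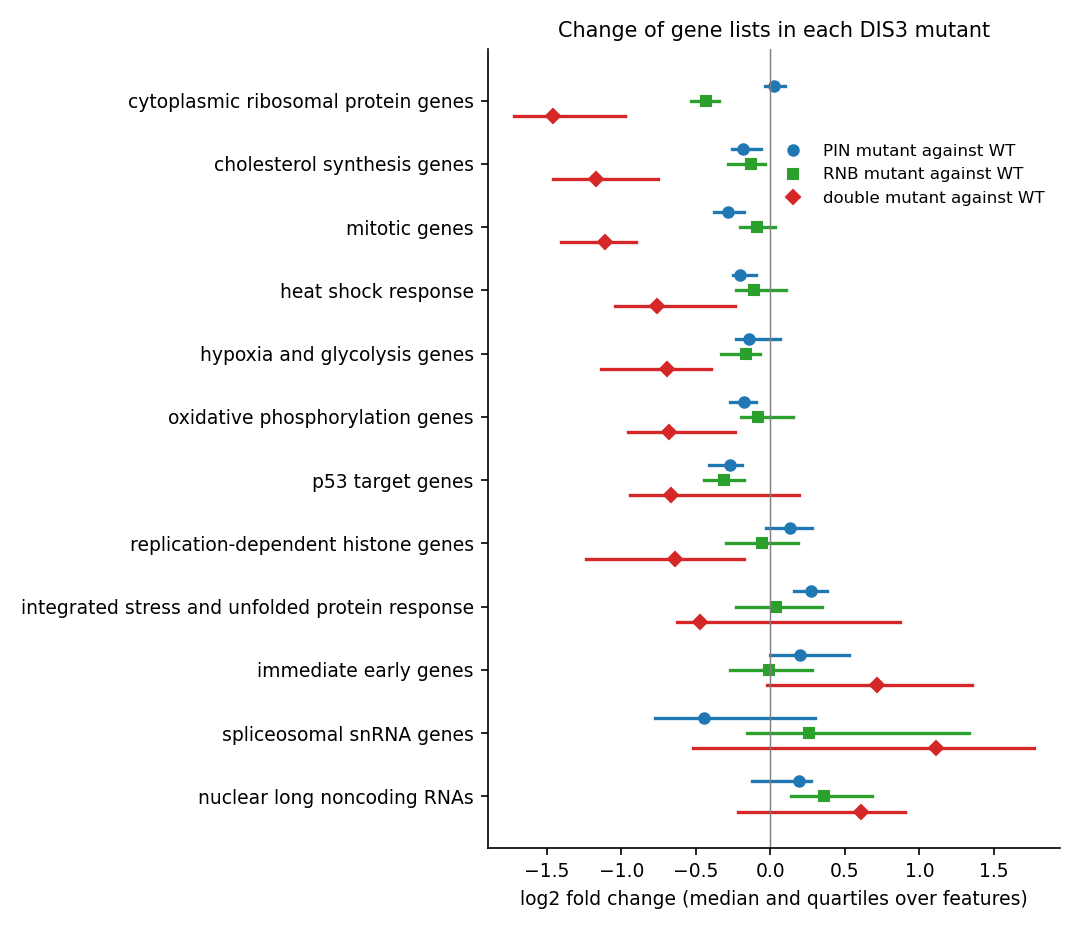
Log2 fold change of 12 of the 25 gene lists (x axis) in the PIN, RNB and double mutants against WT at standard depth, with points for medians and bars for quartiles over genes. Cytoplasmic ribosomal protein genes stood at -1.46 in the double mutant and -0.43 in RNB.

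The deeper runs of the same libraries asked the question again with more features in reach. PROMPT RNA was again higher. Higher snoRNA-downstream RNA and lower ribosomal protein genes were again set calls that did not hold with an estimated inter-gene correlation. Of 40362 features tested, 20681 were higher and 13716 lower (edgeR QL, BH; 21180 and 14109 with the replicate block). Among 18016 protein-coding genes 5322 were higher and 10841 lower (median -0.65). The split moved with the scaling: protein-coding factors shifted all values by 0.64 and gave 25579 higher and 9033 lower, while DESeq2 shifted them by -0.58 and gave 11099 and 16119, and RLE factors shifted them by -0.48 and gave 16709 and 16225. Over the 24007 features tested at both depths the deep values lay below the standard ones by a median of -0.52, with Pearson's r of 0.977 across features, which are not independent replicates. Of 18970 features called at standard depth 17356 were called in the same direction and 271 in the opposite one. No overlap between groups was seen for 34658 features (85.9%, 10% by chance).

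In the deep runs 2377 of 2428 PROMPT regions were higher and 14 lower (median 2.88, 3.53 above the protein-coding median; camera adjusted p = 3e-36, and 0.0069 with an estimated correlation). The PROMPT region beside CEBPG, a bZIP transcription factor gene (T3kB_uc002nup.2), rose from 1.21 ± 0.12 to 120 ± 4 CPM (6.64 ± 0.14, edgeR QL, BH-adjusted p = 8e-22). The one beside EXT1, a heparan sulfate synthesis gene (T3kB_uc003yok.1), rose by 6.55. Regions downstream of snoRNAs were higher at 992 of 1238 (median 1.62; camera adjusted p = 8e-10, but 0.42 with an estimated correlation). snoRNA and scaRNA genes had a median of -0.30, which became 0.34 with protein-coding factors. IGFBP5 (-3.98 ± 0.11, edgeR QL, BH-adjusted p = 2.9e-20) and HIST1H3F (-5.04 ± 0.24, adjusted p = 6.1e-16) fell again. GPC3, a cell-surface proteoglycan gene, fell from 64.7 ± 2.1 to 5.11 ± 0.34 CPM (-3.66 ± 0.11, edgeR QL, BH-adjusted p = 1.4e-19), and GPM6A, a neuronal membrane gene, fell by a log2 value of -3.69.

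Ribosomal protein genes were lower at 77 and higher at 3 of 82 in the deep runs (median -1.95; camera adjusted p = 1.1e-17, but 0.52 with an estimated correlation), with RPL31 at -3.06 and RPS25 at -2.59. Exosome subunits and cofactors were lower at 21 of 26 (median -0.73, also -0.07 relative to protein-coding genes; camera adjusted p = 3.4e-05, but 0.52 with an estimated correlation). The snoRNA and scaRNA list passed the test only with the replicate block (camera adjusted p = 0.065 without and 0.028 with it); its median was -0.30 and its mean 0.11, and 117 of 276 were lower and 93 higher. Markers of blood cells were higher at 15 of 18 (median 1.39; camera adjusted p = 0.018, but 0.53 with an estimated correlation), with HBB, a haemoglobin gene, at 0.140 ± 0.027 CPM in WT and 1.79 ± 0.38 in the double mutant and the leukocyte gene PTPRC at 0.276 ± 0.129 and 1.97 ± 0.46. EGR1 (3.99 ± 0.13) rose and MYC (-1.73 ± 0.11) fell as at standard depth (edgeR QL, BH-adjusted p = 3.1e-19 and 1.8e-13).

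To see what the exonuclease domain alone removes, RNB was compared with WT. PROMPT transcripts were higher, and snoRNA genes were higher and ribosomal protein messages lower in set calls that did not hold with an estimated inter-gene correlation. Of 24007 features, 5277 were higher and 4415 lower (edgeR QL, BH, and 5276 and 4421 with the replicate block), 3301 and 463 by at least 1 log2 unit. The split moved with the scaling, to 4953 and 5024 with RLE factors and 6129 and 3405 with protein-coding factors. Groups were apart for 11956 features (49.8%, 10% by chance). PROMPT regions were higher at 1802 of 2142 and lower at 4 (median 2.53; camera adjusted p = 2.4e-78, and 1.5e-06 with an estimated correlation). Clone-named genes upstream on the opposite strand were higher at 343 of 541 (median 1.64; camera adjusted p = 1.3e-22, and 8.4e-08 with an estimated correlation). Regions downstream of snoRNAs did not pass the set test (191 higher and 17 lower of 1028, median 0.06; camera adjusted p = 0.085). snoRNA and scaRNA genes were higher at 98 and lower at 26 of 208 (median 0.59; camera adjusted p = 1.1e-05, but 0.22 with an estimated correlation). SNORD13 (4.58 ± 0.16, edgeR QL, BH-adjusted p = 6.6e-23), SNORD20 (4.66 ± 0.26, adjusted p = 3.8e-17) and SNORD11B (5.11 ± 0.45, adjusted p = 8.9e-12) rose.

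The PROMPT region beside HSPA5 (T3kB_uc004bpn.2) reached 17.5 ± 1.3 CPM in RNB from 0.102 ± 0.088 in WT (7.14 ± 0.37, edgeR QL, BH-adjusted p = 4.8e-18). The one beside OLA1 (T3kB_uc002uih.2) was at least 46.6-fold higher, and that beside CCDC66, a centrosomal protein gene (T3kB_uc003dhv.2), at least 21.3-fold higher. ZFX-AS1, MIR3191 and RPS20P35 had 0 WT counts and were at least 15.4-fold, 7.55-fold and 6.90-fold higher in RNB. MIR484 (5.24 ± 0.53, edgeR QL, BH-adjusted p = 2.8e-10) and C12orf61 (5.11 ± 0.45, adjusted p = 7.3e-12) rose as well. Among genes that fell in RNB were CHADL (16.6 ± 1.0 to 0.462 ± 0.299 CPM, -5.13 ± 0.30, edgeR QL, BH-adjusted p = 7.8e-17), the zinc-finger genes ZNF22 (-3.89) and ZNF257 (-4.01), the cytokine gene IL18 (-3.63), the sodium-leak channel gene NALCN (-2.88), the adhesion gene CNTN1 (-2.84), the detoxification gene GSTP1 (-2.71) and HMSD (-2.67).

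Among gene lists in RNB, cytoplasmic ribosomal protein genes were lower at 68 and higher at 2 of 80, and at 70 and 2 adjusted over the list alone (median -0.43; camera adjusted p = 1.3e-13, but 0.42 with an estimated correlation), with RPL3 at -0.92. Nuclear long noncoding RNAs were higher at 10 of 17, and lower at 1 adjusted over the list alone (median 0.36; camera adjusted p = 0.015, but 0.42 with an estimated correlation), with FTX at 1.22 and TUG1 at 0.62. The p53 targets were lower at 15 of 24 and 16 adjusted over the list alone (median -0.31; camera adjusted p = 0.0018, but 0.42 with an estimated correlation), with CDKN1A at -0.47. Hypoxia and glycolysis genes (median -0.17; camera adjusted p = 0.016) and markers of fibroblasts and epithelia (median -0.57; camera adjusted p = 0.014) were lower, each at 0.42 with an estimated correlation. EGR1 (2.02 ± 0.18, edgeR QL, BH-adjusted p = 8e-12), ATF3 (0.96 ± 0.08, adjusted p = 8.5e-12) and TRIB3 (1.04 ± 0.10, adjusted p = 2.9e-11) rose, while their list medians for immediate early and stress genes (-0.01 and 0.04) flipped sign with the scaling.

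To see what the endonuclease domain alone removes, PIN was compared with WT. PIN differed from WT at fewer features than the other mutants did, among them CEBPE and LCP1, which were lost in PIN but not in the double mutant. Higher snoRNA-downstream RNA and integrated stress genes and lower mitotic genes and p53 targets were set calls that did not hold with an estimated inter-gene correlation. Of 24007 features, 1024 were higher and 1626 lower (edgeR QL, BH), 229 and 156 by at least 1 log2 unit, and 5779 had an unadjusted p under 0.05. Protein-coding factors gave 1484 and 1242, and DESeq2 gave 444 and 1245. The number higher was 653 without WT replicate 1, 532 without WT replicate 3, 682 without PIN replicate 1 and 556 without PIN replicate 3. The groups did not overlap for 6761 features (28.2%, 10% by chance). PROMPT regions were higher at 44 and lower at 20 of 2142, and at 14 and 6 adjusted over the class alone (median 0.24; camera adjusted p = 0.007, but 0.22 with an estimated correlation). Regions downstream of snoRNAs were higher at 195 and lower at 12 of 1028, and at 262 and 16 adjusted over the class alone (median 0.43; camera adjusted p = 2.2e-11, but 0.34 with an estimated correlation).

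CEBPE, a granulocyte transcription factor gene (chromosome 14, 23586513 to 23588825, minus strand), fell in PIN from 50.0 ± 1.6 to 0.109 ± 0.095 CPM (-8.60 ± 0.24, edgeR QL, BH-adjusted p = 2.2e-25). LCP1, an actin-bundling gene of blood cells, fell from 79.7 ± 1.4 to 1.13 ± 0.57 CPM (-6.11 ± 0.16, edgeR QL, BH-adjusted p = 6.7e-26). CHADL (-5.38), GSTP1 (-4.60), the ubiquitin ligase gene TRIM58 (-4.05), CNTN1 (-3.71), ZNF22 (-3.67) and C14orf39 (-3.55) also fell in PIN (edgeR QL, BH-adjusted p from 3.4e-15 to 0.00025). DDR2, a collagen receptor gene, rose from 3.05 ± 0.54 to 29.2 ± 4.3 CPM (3.24 ± 0.19, edgeR QL, BH-adjusted p = 3.4e-15), as did the hormone genes ADM2 (3.91) and CGA (2.78) and the adhesion gene LSAMP (2.58). LRP2BP, MAATS1 and WWC3 (2.65, 2.48 and 2.42) passed the test on 20 to 23 PIN counts but not without WT replicate 3 (edgeR QL, BH-adjusted p = 0.12, 0.091 and 0.07) or WT replicate 1 (0.054, 0.07 and 0.053), nor did LRP2BP without PIN replicate 3 (0.12) or MAATS1 without PIN replicate 2 (0.11). LINC00167 (2.43, edgeR QL, BH-adjusted p = 0.045) had 12 PIN counts and lost the call without WT replicate 1 (0.18) or 2 (0.17), PIN replicate 1 (0.094), 2 (0.059) or 3 (0.15), or with DESeq2 (0.15). Loci without a symbol that passed had few counts: the PROMPT regions beside OLA1 (T3kB_uc002uih.2, 7 counts against 0), TARS2 (T3kB_uc010pcd.1) and UTP3 (T3kB_uc003hfo.2), and CTA-397H3.3, lost the call without WT replicate 3 (edgeR QL, BH-adjusted p = 0.093, 0.097, 0.074 and 0.11), and all but the region beside UTP3 without PIN replicate 1 (0.08, 0.15 and 0.15); each also lost it without WT replicate 1 or 2 (0.057 to 0.087). RP11-11N9.4 fell by a log2 value of -4.96 ± 0.40 (edgeR QL, BH-adjusted p = 3.3e-11).

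Among gene lists in PIN, mitotic genes were lower at 15 of 28, and at 21 adjusted over the list alone (median -0.28; camera adjusted p = 2.9e-08, but 0.29 with an estimated correlation), with the kinase gene PLK1 at -0.42. The p53 targets were lower at 12 of 24, and at 19 adjusted over the list alone (median -0.27; camera adjusted p = 7.5e-06, but 0.21 with an estimated correlation), with BAX at -0.93 and CDKN1A at -0.46. Integrated stress genes were higher at 12 and lower at 1 of 27, and at 18 and 2 adjusted over the list alone (median 0.27; camera adjusted p = 2.1e-05, but 0.29 with an estimated correlation), with TRIB3 at 1.06 and CHAC1 at 0.79. Immediate early genes were higher at 6 and lower at 3 of 24 (median 0.20; camera adjusted p = 0.036, but 0.28 with an estimated correlation). Heat shock (-0.20), oxidative phosphorylation (-0.18), cholesterol synthesis (-0.18), spliceosomal snRNA (-0.44) and short Pol III RNA (-0.28) lists had lower medians (camera adjusted p = 0.00089, 0.00021, 0.0013, 0.0023 and 0.017, and 0.29, 0.47, 0.21, 0.45 and 0.29 with an estimated correlation). The lncRNAs MALAT1 (0.89 ± 0.09, edgeR QL, BH-adjusted p = 8.3e-09) and NEAT1 (0.82 ± 0.10, adjusted p = 1.6e-07) were higher in PIN.

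RNB was compared with PIN to contrast the 2 activities directly. PROMPT RNA was higher in RNB, and CEBPE and LCP1 separated the lines. Of 24007 features, 5774 were higher and 4449 lower in RNB (edgeR QL, BH), and the groups did not overlap for 12699 (52.9%, 10% by chance). PROMPT regions were higher at 1696 and lower at 11 of 2142 (median 2.26; camera adjusted p = 2.6e-64, and 3.2e-06 with an estimated correlation), whereas regions downstream of snoRNAs were lower at 285 and higher at 161 of 1028 (median -0.36; camera adjusted p = 0.038, but 0.69 with an estimated correlation). snoRNA and scaRNA genes were higher at 104 and lower at 16 of 208 (median 0.63; camera adjusted p = 1.5e-05, but 0.23 with an estimated correlation). CEBPE stood at 253 ± 6 CPM in RNB and 0.109 ± 0.095 in PIN (10.94 ± 0.18, edgeR QL, BH-adjusted p = 4.2e-33) and LCP1 at 82.7 ± 2.4 and 1.13 ± 0.57 (6.17 ± 0.16, adjusted p = 8.1e-27). SNORD13 (5.31), SNORD111B (4.98), SNORD121B (4.98), DNAJC27-AS1 (4.78) and LINC00441 (4.77) were higher in RNB, and MIR3912 was at least 9.36-fold higher against 0 counts. The PROMPT region beside CDCA4, a cell-cycle gene (T3kB_uc001yqa.2), stood at 26 ± 2.7 CPM in RNB and 0.266 ± 0.082 in PIN (6.49 ± 0.26, edgeR QL, BH-adjusted p = 3.9e-21). PCDH19, a protocadherin gene (-2.95), DDR2 (-2.96), TMEFF2 (-2.99), PTGER3 (-3.09), MUC7 (-2.92), DDIT4L (-2.83) and PADI4 (-2.73) were lower, as was ASPA (-2.85), whose call was lost without RNB replicate 2 or 3 (edgeR QL, BH-adjusted p = 0.069 and 0.073). DIS3 was higher in RNB (0.36 ± 0.08, edgeR QL, BH-adjusted p = 0.00076).

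Overlap between the mutants was counted with the shared WT libraries in mind. RNB and the double mutant shared 4361 features higher and 3884 lower, with 429 opposite, where independent lists would share 2224 and 1628. PIN and RNB shared 318 higher and 803 lower, with 301 opposite, against 225 and 299 for independent lists. PIN and the double mutant shared 2252 called features, of which 505 were higher in both, 513 opposite and the others lower in both, against 432 higher and 599 lower for independent lists. The covariance of log2 fold changes across features was 1.45 for RNB with the double mutant, 0.174 for PIN with RNB and 0.390 for PIN with the double mutant. It was 0.0222, 0.0223 and 0.0223 in 10 simulations of unchanged groups that shared WT libraries drawn from the WT means. Pearson's r across features, which are not independent replicates, was 0.75, 0.28 and 0.41, and 0.45, 0.50 and 0.44 in the simulations. The simulated fits held 17894 to 18082 features, not 24007, and no changed ones. Their 0 shared calls do not test the overlap. The real WT libraries were not kept in these fits, and a larger deviation of them was not simulated. Parting 3 WT libraries cannot leave 2 for each comparison, so part of the excess overlap may still come from the shared controls.

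To ask what the PIN mutation adds where the exonuclease is already inactive, the double mutant was compared with RNB. PROMPT RNA rose further, and snoRNA-downstream RNA rose and mitotic genes fell in set calls that did not hold with an estimated inter-gene correlation. Of 24007 features, 8403 were higher and 8194 lower (edgeR QL, BH), and protein-coding factors, which shifted values by 0.27, gave 10730 and 5644. Values of the groups were apart for 17161 features (71.5%, 10% by chance). PROMPT regions were higher at 1588 and lower at 16 of 2142 (median 0.95; camera adjusted p = 4.3e-19, and 0.00025 with an estimated correlation), and regions downstream of snoRNAs at 812 and 40 of 1028 (median 1.99; camera adjusted p = 1.3e-25, but 0.1 with an estimated correlation). ZNF22 (0.544 ± 0.194 to 12.2 ± 1.0 CPM, 4.41 ± 0.30, edgeR QL, BH-adjusted p = 6.5e-15), ZNF257 (4.47), DUX4L13 (4.76) and the phototransduction gene PDE6C (5.01) were higher. MYOM2, a sarcomere gene (48.7 ± 2.6 to 4.28 ± 0.79 CPM, -3.47 ± 0.15, edgeR QL, BH-adjusted p = 5.9e-20), IGFBP5 (-3.21), HIST1H3F (-3.12), HLA-DPA1 (-2.62), IQSEC2 (-2.55) and the kinase gene MAPK4 (-2.48) were lower. Immediate early genes were higher at 16 and lower at 4 of 24 (median 0.84; camera adjusted p = 0.0017, but 0.09 with an estimated correlation), with EGR1 at 2.59 and JUNB at 1.66, and mitotic genes were lower at 27 of 28 (median -1.10; camera adjusted p = 9.3e-10, but 0.25 with an estimated correlation).

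The PIN by RNB interaction asked whether the double mutant differed from the sum of the single mutants on the log2 scale. PROMPT RNA exceeded that sum, and snoRNA-downstream RNA above it and ribosomal protein, mitotic and cholesterol genes below it were set calls that did not hold with an estimated inter-gene correlation. Of 24007 features, 4154 were above and 6420 below the sum (edgeR QL, BH), and protein-coding factors, which shifted values by 0.21, gave 5740 and 4598. PROMPT regions were above it at 388 and below at 13 of 2142 (median 0.70; camera adjusted p = 7.4e-14, and 0.00084 with an estimated correlation), and regions downstream of snoRNAs at 666 and 44 of 1028 (median 1.48; camera adjusted p = 7.3e-21, but 0.13 with an estimated correlation). Ribosomal protein genes were below it at 68 of 80, and at 69 adjusted over the list alone (median -0.99; camera adjusted p = 2.9e-17, but 0.36 with an estimated correlation), mitotic genes at 25 and above it at 1 of 28 (median -0.81; 4.1e-07, but 0.36), and cholesterol synthesis genes at 18 and 1 of 24 (median -0.89; 5.1e-05, but 0.11), the last 2 lists also adjusted over the list alone. CEBPE, which PIN lost and RNB raised, stood above the sum (7.24, edgeR QL, BH-adjusted p = 2.7e-19), as did LCP1, which PIN alone lost (5.96 ± 0.20, adjusted p = 2.1e-22). The sum predicts under 3 double-mutant counts for RP6-99M1.2 and for ZNF22, GSTP1, CHADL and ZNF257, which were low in both single mutants. The size of their excess is therefore uncertain, as for 252 of the 4154 features above the sum. ADM2 (-4.25), CGA (-3.72), MYOM2 (-3.67), the cholesterol transport gene TSPO (-3.54), IGFBP5 (-3.31) and SAMD9 (-3.07) stood below it. The clone-named RP6-99M1.2 (6.93) lost its call without WT replicate 2 or 3 (edgeR QL, BH-adjusted p = 0.057 and 0.054). DIS3 stood above the sum (0.53 ± 0.12, edgeR QL, BH-adjusted p = 0.00051).

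NEAT1, the RNA scaffold of paraspeckles, is made as a short and a long isoform that share their 5' end (chromosome 11, plus strand). A short and a long annotated entry were read, chosen after their values were seen. The short entry (ENST00000499732.1, 65190245 to 65192232) stood at 34.2 ± 5.6 CPM in WT, 62.3 ± 22.4 in PIN, 96.8 ± 20.6 in RNB and 372 ± 3 in the double mutant. The long entry (ENST00000501122.2, 65190269 to 65213011) stood at 658 ± 7, 1160 ± 269, 785 ± 47 and 1016 ± 94 CPM. In a fit over all transcripts with its own TMM factors, the short entry was higher in the double mutant (3.80 ± 0.12, edgeR QL, BH-adjusted p = 9.5e-42), in RNB (1.58 ± 0.12, adjusted p = 3.9e-18) and in PIN (0.90 ± 0.13, adjusted p = 1.6e-07). In the deep runs it went from 46.2 ± 7.5 to 328 ± 16 CPM (3.41 ± 0.11, edgeR QL, BH-adjusted p = 5.9e-17), and its interaction passed the test (1.32 ± 0.17, edgeR QL, BH-adjusted p = 7.4e-10). Most of the short entry lies inside the long one, so reads there were counted for both and cannot be given to either isoform. The counts of the short entry were subtracted from those of the long one. The remainder stood at 623 ± 10 CPM in WT, 1098 ± 247 in PIN, 688 ± 52 in RNB and 644 ± 95 in the double mutant, and in the deep runs at 801 ± 28 in WT and 567 ± 114 in the double mutant. It was higher in PIN (0.85 ± 0.08, edgeR QL, BH-adjusted p = 7e-13, and 0.82 ± 0.10, adjusted p = 4e-07, with the factors of the features). In the other mutants its change depended on the scaling: 0.40 (edgeR QL, BH-adjusted p = 2.4e-05) against 0.05 (adjusted p = 0.67) with the factors of the features in the double mutant, 0.08 (0.47) against -0.50 (0.0012) in the deep runs, and 0.21 (0.039) against 0.14 (0.29) in RNB.

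**Figure D4:**
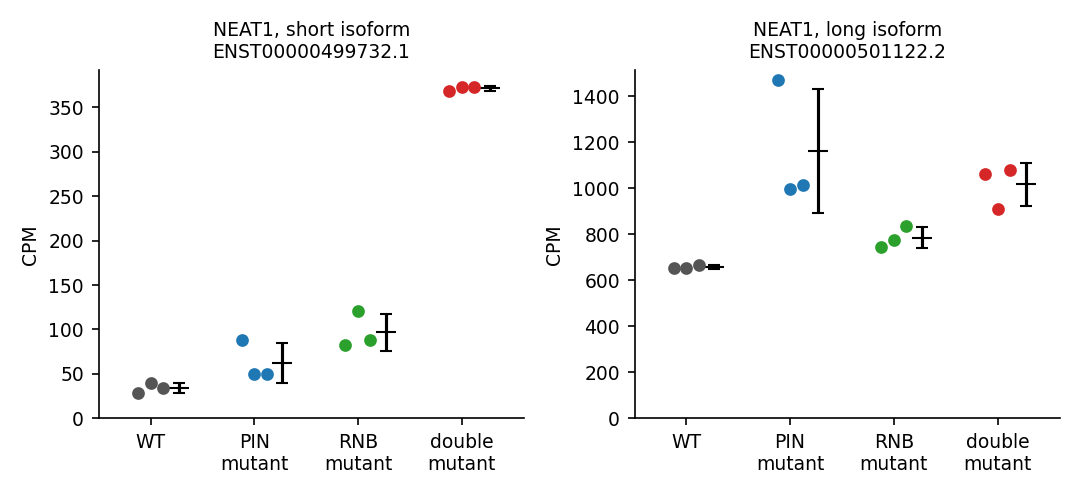
CPM of the short and the long NEAT1 entry (y axis) by genotype at standard depth, with a point for each of 3 libraries and bars for the mean and SD. The short entry went from 34.2 in WT to 372 in the double mutant.

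Pol II IPs were first set against their mocks to see where the antibody enriched chromatin. More protein-coding genes were enriched than depleted. Of 54239 features, 19454 were higher and 21766 lower in the IP in WT, and 18972 and 21942 in the double mutant (edgeR QL, BH). Among protein-coding genes 9982 and 6526 were higher and lower in WT, and 10015 and 6447 in the double mutant. RLE factors shifted these values by 0.12 and 0.14, and DESeq2 by 0.14 and 0.16. Over all features this turned the majority. In WT RLE factors gave 20764 higher and 18882 lower, and DESeq2 20756 and 17539. In the double mutant they gave 20380 and 18635, and 20375 and 17283. In WT the U3 snoRNA gene SNORD3B-2 was 145-fold enriched, a U3 copy on chromosome 17 198-fold and MIR320A 216-fold, and in the double mutant RNU11 was 193-fold and RNU1-85P 189-fold enriched. The milk casein gene CSN1S1 (-2.01 ± 0.21), the matrix gene DCN (-1.82 ± 0.23) and IL2 (-1.80 ± 0.20) were lower in the WT IP, and the casein gene CSN3 (-1.82 ± 0.19) in that of the double mutant (edgeR QL, BH-adjusted p from 1e-07 to 9.8e-07). The groups did not overlap for 42942 features in WT (79.2%) and 42381 in the double mutant (78.1%), against 10% by chance.

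Pol II in the double mutant was compared with WT to ask whether changes in RNA came with changes in transcription. Pol II was lower on EGR1, EGR2, EGR3 and the histone gene HIST1H3F and higher on the cytokine gene TNF. Of 52359 features, 1873 were higher and 2858 lower (edgeR QL, BH), and 5162 and 5084 with the replicate block. Only 95 and 202 changed by at least 1 log2 unit. The counts depended on single libraries: 7978 higher and 5955 lower without WT replicate 1, 425 and 1418 without WT replicate 2, 359 and 1136, 575 and 893, and 216 and 586 without double-mutant replicate 1, 2 or 3. Library size alone as the scaling gave 1409 and 3569. The groups did not overlap for 15787 features (30.2%, 10% by chance).

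TNF (chromosome 6, 31543344 to 31546113, plus strand) rose from 2.33 ± 0.10 to 13.2 ± 0.4 CPM in the Pol II IP (2.51 ± 0.10, edgeR QL, BH-adjusted p = 8e-07). HIST1H3F fell from 3.98 ± 0.32 to 0.295 ± 0.060 CPM (-3.76 ± 0.17, edgeR QL, BH-adjusted p = 1.6e-06), as did its RNA. EGR1 fell from 139 ± 19 to 35.2 ± 9.0 CPM (-1.98 ± 0.15, edgeR QL, BH-adjusted p = 9.6e-05), against the rise of its RNA, and EGR3 (-1.74), EGR2 (-1.26) and FOSB (-1.16), further immediate early genes, fell too. Other falls were at ENTPD8 (-1.75), a nucleotide-hydrolysing enzyme, MFSD7 (-1.64), VMO1 (-1.48), FAM132A (-1.43) and THEM6 (-1.43). The largest rises besides TNF were mitochondrial genes such as MT-TG (3.08) and MT-ND3 (2.06), and hsa-mir-6723 (1.43), which lies in a nuclear copy of mitochondrial sequence. All 15 mitochondrially encoded genes were higher (median 1.56; camera adjusted p = 1.6e-13, but 0.7 with an estimated correlation). The mitochondrial share of counts was 0.0510 to 0.0973% in the double-mutant IPs and 0.0204 to 0.0328% in the WT IPs.

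PROMPT regions carried slightly more Pol II, 378 higher and 60 lower of 2470 (median 0.17; camera adjusted p = 8.1e-10, but 0.97 with an estimated correlation). snoRNA and scaRNA genes carried less, 43 lower and 2 higher of 434 (median -0.22; camera adjusted p = 9.4e-06, but 0.59 with an estimated correlation), and tRNA genes had a median of 0.12 (camera adjusted p = 0.04, but 0.06 with the replicate block and 0.8 with an estimated correlation). Regions downstream of snoRNAs had a median of 0.02, which flipped sign with library size alone (camera adjusted p = 0.74). Cytoplasmic ribosomal protein genes were lower at 18 of 83, and at 37 adjusted over the list alone (median -0.26; camera adjusted p = 1.5e-08, but 0.89 with an estimated correlation), with RPS19 at -0.69. Immediate early genes (median -0.27; camera adjusted p = 0.00015), mitotic genes (-0.21; 5.6e-05), snoRNA host genes (-0.20; 0.0017) and hypoxia and glycolysis genes (-0.23; 0.0017) were lower, each at 0.89 with an estimated correlation. DNA replication (-0.11; 0.022), ribosome biogenesis (-0.11; 0.023), cholesterol synthesis (-0.17; 0.032) and blood cell (-0.16; 0.023) lists were lower as well, at 0.89, 0.89, 0.89 and 0.7 with an estimated correlation.

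The difference of IP over mock between genotypes removed what the mocks shared with the IPs. TNF gained Pol II, and EGR1 and EGR3 lost it. Of 54239 features, 50 were higher and 99 lower (edgeR QL, BH), and 27 and 56 with the replicate block, 19 and 16 with RLE factors, and 142 and 220 with DESeq2, with 5447 at an unadjusted p under 0.05. Single libraries moved these numbers: 1132 and 254 without WT IP replicate 1, 16 and 12 without WT IP replicate 2, 16 and 14, 17 and 9, and 14 and 9 without double-mutant IP replicate 1, 2 or 3. They were 26 and 31, 23 and 22, and 26 and 65 without WT mock replicate 1, 2 or 3, and 19 and 31, 23 and 92, and 50 and 31 without double-mutant mock replicate 1, 2 or 3. TNF rose by 2.80 ± 0.19 (edgeR QL, BH-adjusted p = 2.9e-06), and IL32 (1.84), LINC00632 (1.31), TNFRSF9 (1.25) and the NF-kappaB inhibitor gene TNFAIP3 (1.15) also rose. HIST1H3F (-3.63), EGR1 (-2.12), ENTPD8 (-2.09) and EGR3 (-1.94) fell (edgeR QL, BH-adjusted p = 9.5e-05, 0.0045, 0.00013 and 0.0006). IL8 (1.49), KRT8P9 (1.36), DUSP8 (1.29), THEM6 (-1.98), SFRP5 (-1.68), MFSD7 (-1.66) and PNPLA2 (-1.52) passed the test but not without double-mutant IP replicate 3 (edgeR QL, BH-adjusted p = 0.051, 0.059, 0.11, 0.084, 0.066, 0.066 and 0.13). KRT8P9, DUSP8, THEM6 and PNPLA2 also lost it without WT IP replicate 2, double-mutant IP replicate 2 or WT mock replicate 1 (edgeR QL, BH-adjusted p from 0.053 to 0.13) and with RLE factors (0.076, 0.087, 0.057 and 0.076), and SFRP5 and MFSD7 without double-mutant IP replicate 2 (0.054 each). The PROMPT region beside C12orf5, a p53-regulated glycolysis gene (T3kB_uc001qmp.2), rose by 1.49 ± 0.20 (edgeR QL, BH-adjusted p = 0.0028). PROMPT regions were higher at 11 and lower at 0 of 2470 (median 0.21; camera adjusted p = 1.2e-11, but 0.96 with an estimated correlation), at 32 and 5 adjusted over the class alone, and mitochondrial genes had a median of -1.27 (camera adjusted p = 0.16), which turned to 0.60 without double-mutant mock replicate 3.

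**Figure D5:**
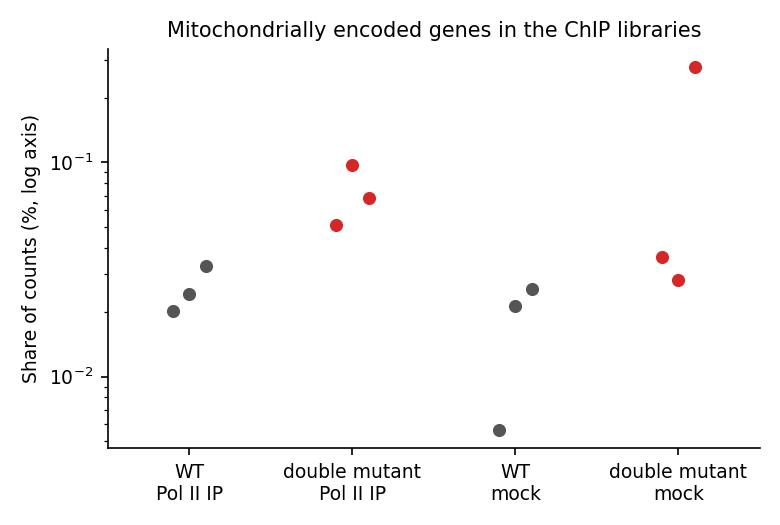
Percent of counts on mitochondrially encoded genes (y axis, log scale) in each Pol II IP and mock library, with a point for each library. The double-mutant IPs lay between 0.0510 and 0.0973% and the WT IPs between 0.0204 and 0.0328%, and the mocks between 0.0281 and 0.278% and between 0.00564 and 0.0255%.

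RNA and Pol II changes between the double mutant and WT were set side by side over 39572 features of the deep runs. Most features with changed RNA had no Pol II call in the same direction. Many features carry little Pol II over background, which compresses Pol II changes, so the features called higher in the IP than in the mock in either genotype were also read alone: of 15862 of these with changed RNA, 2060 had a Pol II call in the same direction, and 3960 with the replicate block in the Pol II fit. The 20394 features with higher RNA had a median Pol II change of 0.03 (-0.00937 in random lists matched on Pol II signal, percentile 100), and the 13504 with lower RNA one of -0.01 (0.0287, percentile 0). Of the higher ones 951 gained and 731 lost Pol II, and of the lower ones 661 gained and 1381 lost it (edgeR QL, BH). With the replicate block in the Pol II fit these numbers were 2584 and 1375, and 1764 and 2427. Pearson's r was 0.174 and Spearman's rho 0.168 across features, which are not independent replicates. Protein-coding genes with higher RNA had a median of -0.00404 (-0.0320 in random lists, percentile 100) and those with lower RNA one of 0.00993 (0.0176, percentile 0), so both medians lay near 0 (r = 0.0477). Without WT Pol II replicate 1 these protein-coding percentiles were 0 and 100 (r = -0.0815), and among protein-coding genes with the IP above the mock they were 0.49 and 76.98 (r = -0.0136), so no direction is given for them. PROMPT regions with higher RNA had a median Pol II change of 0.175 (0.173 in random lists, percentile 99.19), and r across PROMPT regions was 0.306. These were 2377 of the 2428 PROMPT regions, and the random lists were drawn from the same 2428. Each random list thus held nearly the same members, so this percentile cannot tell whether Pol II rose with PROMPT RNA.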

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

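The tests in this part were chosen after the results were seen, except the comparison of ribosomal protein genes with genes of like length and level, which was set before.

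Features stood out where the effect of the PIN mutation in the RNB mutant differed from its effect in the WT background, by the interaction test. By class the median difference in log2 was 0.70 for PROMPT regions, 1.48 for regions downstream of snoRNAs (1.55 for those with no annotated exon inside), 0.34 for clone-named genes, 0.46 for those upstream on the opposite strand, 0.89 for those elsewhere, 0.20 for those overlapping a gene, 0.37 for other genes and -0.22 for protein-coding genes, which became -0.00 with TMM factors from protein-coding genes. By list it was -0.99 for cytoplasmic ribosomal protein genes, -0.90 for replication-dependent histone genes, -0.89 for cholesterol synthesis genes, -0.81 for mitotic genes, -0.45 for hypoxia and glycolysis genes, -0.41 for heat shock genes, -0.40 for exosome subunits and cofactors, -0.37 for integrated stress genes, -0.34 for oxidative phosphorylation genes and -0.24 for DNA replication genes. Upward differences were 0.46 for immediate early genes, 0.53 for markers of fibroblasts and epithelia, 0.57 for spliceosomal snRNA genes and 1.47 for markers of blood cells. In the interaction 10574 features were called, and 1 of 40 splits of the libraries drawn gave as many, the real one, with 0 in the highest other. These splits mix the 4 genotypes within each group, so the large differences between genotypes enter the spread and few calls were to be expected, and they do not test the interaction against chance.

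PROMPT regions were higher in the double mutant, which genomic DNA or scaling might produce. Genomic DNA would add reads evenly over the regions, but the 607 regions with the most WT Pol II over mock gained 5.96 times the median CPM of the 607 with the least (95% bootstrap interval 5.15 to 6.91). Scaling would move PROMPT regions with protein-coding genes, but the lowest median above protein-coding genes over scalings and depths was 3.53 (spread between libraries 0.117). A scaling factor common to a library cancels in this difference, so trying several scalings adds little to it. The value shows a rise relative to protein-coding genes, and without spike-ins the absolute change was not tested. A candidate explanation is loss of decay of RNA made at active promoters, a hypothesis drawn from these data, in which decay itself was not tested. Because each genotype was 1 cell line, a difference between lines stays open.

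Ribosomal protein genes were lower in the double mutant, which transcript length, level or scaling might produce. Lists of other protein-coding genes nearest in exonic length and CPM had a median of -0.77 (95% of them from -1.02 to -0.57) against -1.46 for the ribosomal protein genes, which lay at percentile 0 among 10000 lists. Relative to protein-coding genes the highest median over scalings and depths was -1.11 (spread 0.165). Common scaling factors cancel here too, so only a fall relative to protein-coding genes is shown. Slower growth of this line and loss of these messages through DIS3 were not tested against each other, and both stay open.

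Mitochondrially encoded genes were higher in the Pol II IP of the double mutant, which more mitochondrial DNA in the chromatin would produce. The median difference was 1.56 in the IP and 2.81 between the mocks, and -1.27 for IP over mock, but without double-mutant mock replicate 3, which held the most, it was 0.97 between the mocks and 0.60 for IP over mock. All 3 double-mutant mocks (0.0361, 0.0281 and 0.278% of counts) lay above the highest WT mock (0.00564, 0.0215 and 0.0255%), where an exact test of 3 against 3 cannot give a p under 0.1. By edgeR QL 0 of the 15 genes were called between the mocks and 0 for IP over mock, with 15 and 0 at an unadjusted p under 0.05 and 0 by DESeq2 for IP over mock. Between the mocks 15 were called without WT IP replicate 1 and 13 without double-mutant mock replicate 2. Because the sign of IP over mock rests on 1 library, more mitochondrial DNA and more Pol II there cannot be told apart.

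With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Fits of the compared libraries alone called 17120 features for the double mutant against WT at standard depth, 34397 deep, 3344 for PIN, 9585 for RNB, 10288 for RNB against PIN, 14938 for the double mutant against RNB, 4731 in Pol II, and 39977 and 40521 for IP against mock in WT and the double mutant. In each case 1 of 10 splits gave as many, the real one, and the highest other gave 0, also among the 4 splits that part the 3 numbered pairs. The other splits mix the compared groups, so their large differences enter the spread, few calls were to be expected and none of these comparisons is tested against chance. For IP over mock 149 features were called and 3 of 40 splits gave as many, the highest other 1173, so chance cannot be excluded there either. These splits ignored the numbered pairs of the IPs and also mix the genotypes, so they do not measure how likely chance is. The reason for the larger split was not tested.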

How the results depend on the processing

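TMM factors from protein-coding genes, summed isoforms, NEAT1 without shared reads, and for Pol II set against RNA the features with the IP above the mock and the replicate block, were chosen after the data were seen; the block left the percentiles of the Pol II medians at 100 and 0 for all features and for protein-coding genes, and at 99.12 for PROMPT regions with higher RNA and 0.25 for the 14 with lower RNA. Across the alternatives and left-out libraries 2164 leave-one-out values of named genes kept their direction and side of the threshold, 107 lost a call and 3 gained one, and among other planned values 1786 kept it, 19 lost and 5 gained a call and 1 turned. The cause of the changes below was not tested. ERCC scaling was not run, as no ERCC entry was found. Shallow double-mutant libraries (2378121 to 4007602 counts) limit calls for features near 1 CPM.

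A threshold of 1 log2 unit left 3889 lower features for the double mutant at standard depth, 8563 lower in the deep runs, 229 higher and 156 lower for PIN, 3301 and 463 for RNB, 3184 and 873 for RNB against PIN, 2332 lower for the double mutant against RNB and 2069 below the sum in the interaction. In the deep runs DESeq2 called 11099 higher, a filter of CPM 1 in 3 libraries, which tests fewer features, 12961, and protein-coding factors 9033 lower. PIN had 444 higher with DESeq2, 520 with isoforms summed and 1595 in a fit of the 2 groups, and 532 to 770 with 1 library left out (532 without WT replicate 3). DESeq2 called 2599 above the sum in the interaction. With the replicate block Pol II had 5162 higher and 5084 lower features, and leaving out 1 library gave 216 to 7978 higher and 586 to 5955 lower. IP over mock had 27 higher and 56 lower with the block, 19 and 16 with RLE factors, 142 and 220 with DESeq2, and 14 to 1132 and 9 to 254 with 1 library left out.

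The PROMPT median moved to 3.85 with protein-coding factors and to 3.37 to 3.52 with 1 library left out for the double mutant at standard depth (3.72 to 3.85 above protein-coding genes), to 2.40 with RLE factors, 3.52 with protein-coding factors and 2.69 to 2.91 with 1 library left out in the deep runs, and to 2.41 to 2.51 for RNB with 1 library left out (2.52 to 2.62 above protein-coding genes). For RNB against PIN it was 2.16 to 2.24 with 1 library left out. For the double mutant against RNB it moved to 1.03 with RLE factors, 1.22 with protein-coding factors and 0.87 to 0.97 with 1 library left out. In the interaction it moved to 0.91 with protein-coding factors and 0.58 to 0.73 with 1 library left out. Downstream of snoRNAs the deep median moved to 1.14 with RLE and 2.27 with protein-coding factors.

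Direction turned with protein-coding factors for the deep median of snoRNA and scaRNA genes (0.34), the protein-coding median of PIN (0.0342) and of the double mutant against RNB (0.00062), and deep DIS3 (0.64; 0.34 with a filter of CPM 1 in 3 libraries). The tRNA median above protein-coding genes for the double mutant against RNB was -0.0431 to 0.502 with 1 library left out, the lowest without double-mutant replicate 3. Without WT Pol II replicate 1 the percentiles of the Pol II medians of protein-coding genes with higher and lower RNA were 0 and 100, and the latter was 2.77 with IP over mock. With only features whose IP lay above the mock they were 0.49 and 76.98.

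An estimated inter-gene correlation left 0 lists past the camera threshold for the double mutant at standard depth (8 at the preset value, 19 with fry), 0 deep (17), 0 for PIN (9), 0 for RNB (6, 10 with fry), 0 for RNB against PIN (4, 11 with fry), 0 for the double mutant against RNB (11, 19 with fry), 0 for the interaction (14), 0 for Pol II (11, 0 with fry), 0 for IP over mock (5, 0 with fry) and 0 for IP against mock in WT (17) and the double mutant (18). The list calls therefore rest on the preset correlation.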

Other observations

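No further hypothesis was tested in this part. Deep and standard runs of the same number differed by a chi-square per degree of freedom of 1.10 to 1.25, and runs of other numbers by 2.715 to 13.16. Standard libraries of 1 group differed by 1.786 to 12.68. The double-mutant libraries held fewer counts than the others at standard depth (2378121 to 4007602 against 6227876 to 7932501) and in the deep runs (15240573 to 23732244 against 45187388 to 51855786), and their TMM factors were 1.27 to 1.35 and 1.35 to 1.55 against 0.873 to 0.953 and 0.672 to 0.721. The PROMPT share of counts was 0.240 to 0.268% in PIN and 0.216 to 0.239% in WT.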
